A study of Homo sapiens with 6 samples.

How the data were processed

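Expression was measured in 6 cultures of MCF-7 cells, an oestrogen receptor positive human breast cancer line, on Affymetrix arrays that carry probes along whole transcripts. Per the labels, 3 cultures received 200 µM Lacciac Acid A (the labels' spelling) in medium renewed every day and 3 received none. The series' design text gives 5 days of treatment, within 7 days of culture per the labels' protocols. Biotin-labelled cRNA was made from total RNA and hybridised, per the labels' protocols. Samples were grouped by the agent that the labels name, and each carries the number 5, 7 or 8 in its title.

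The deposited table holds 1 log2 value per probe set and array, and the authors' processing produced it: per the submitters' processing notes, GCOS, Partek 6.5 and RMA were used, with no role or order given. RMA corrects background, quantile-normalises the arrays together and summarises probes on the log2 scale. The genome build and annotation are not given in the sources used here, so no coordinates are printed. The table has 33297 rows with values from 2.75 to 14.2, and the median over all rows lay between 6.20 and 6.27 on every array. Scanner files were not used here, so background correction could not be varied, no detection calls or scan dates were at hand, and the number of arrays limits the precision.

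Probe sets were named from GEO's platform annotation. Of the rows, 19460 had exactly 1 gene symbol, 1754 had several and 12083 had no listed gene. Control probe sets could not be told apart from other unlisted rows. Rows with several or no symbols were not named and not tested in the main comparison. Of the rows with 1 symbol, 19429 matched the RefSeq gene table by gene ID. For the 769 genes with more than 1 probe set, the probe set with the highest mean over all 6 arrays stood for the gene, which left 18417 genes. In 145 of these genes at least 2 probe sets held identical values on every array and are no separate evidence.

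Treated and untreated arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. "Rose" and "fell" are used only for genes past that threshold. Values are given as log2 signal, mean ± SD over 3 arrays per group, and changes as treated minus untreated on the log2 scale with the standard error from limma. RMA signals compress changes of dim genes. The labels do not say whether the arrays of a group came from independent experiments beyond the 2 passages the design text mentions, so p-values measure the spread between these cultures.

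In total, 18 gene lists and 3 lists of markers of other cell types were written before the data were examined, as were the comparison, the alternatives and the rule for naming genes. The lists hold 630 different genes, of which 564 were measured with a single-symbol probe set. Each of the 18 lists was tested with limma's camera function (preset correlation of 0.01, two-sided, adjusted over 18 lists), with camera and an estimated correlation between the genes, and with fry. Camera compares a list with all other genes. The fry p asks whether the members move one way on balance, and its mixed p whether they change in either direction. Genes were named by this rule: the 12 highest and 12 lowest changes among genes past the threshold whose 3 treated values all lay on 1 side of the 3 untreated values, up to 4 members past the threshold from each list with the largest changes (or the 2 with the smallest p where none passed), and DNMT1, UHRF1, ESR1, PGR, TFF1, MKI67, CYP1A1, NQO1 and GSTP1 in any case. Other genes are named only where a list had 5 or fewer calls, for further members of the lists on DNA methylation, oestrogen receptor, aryl hydrocarbon receptor, luminal, mesenchymal and fibroblast genes, or in the closing section, and these were chosen after their values were seen.

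Per the design text, treated and untreated cells of a set shared a passage, and no label ties a number to a set, so the fit with the number as a block is an alternative. No 2 arrays held identical values, and the correlations between arrays over all rows ran from 0.9936 to 0.9959. Further alternatives were other scalings between arrays, another rule for genes with several probe sets, a filter on dim genes (30th percentile), other variance priors, other thresholds and leaving out each array.

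The scripts were tested on simulated data with the real genes' means. Each gene's spread was drawn at random from the distribution that limma fitted to the real genes, whatever the gene's level. In 10 simulations of this comparison 200 of 18417 genes were changed. Of changes of 1 (log2) 99.2% were recovered, of changes of 0.5 76.1% and of changes of 0.35 30.3%. Of all calls 5.72% were false. These simulations met the assumptions of the main fit, so the rates may be worse in real data. A list of 40 genes shifted by 0.2 was called in 10 of 10 simulations, and 0 of 190 unshifted lists were called, with genes simulated as independent.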

Results

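MCF-7 cells were grown with 200 µM Lacciac Acid A for 5 days (3 cultures) or without it (3 cultures), and the transcriptome of each culture was read on 1 array. The name was read as laccaic acid A, an anthraquinone pigment of the lac insect reported to inhibit DNA methyltransferase 1, the enzyme that copies DNA methylation after replication. The comparison asks which transcripts differed between treated and untreated cells of this line, in which some gene promoters are methylated. The arrays were alike: over all 33297 rows, correlations within a group had a median of 0.9955 and those between the groups a median of 0.9943, and the lowest within-group value (0.9947) lay above the highest between-group value (0.9946).

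Treatment was accompanied by a change in 581 of 18417 genes, of which 303 (1.65%) rose and 278 (1.51%) fell. Most changes were small. The median size among the 581 genes was 0.45 on the log2 scale, and 20 genes rose and 20 fell by at least 2-fold. The largest rise was that of CYP1A1 (probe set 7990391), which encodes a xenobiotic-metabolising cytochrome P450, and the largest fall was that of TGFB2, which encodes a transforming growth factor beta ligand. In all 581 genes the 3 treated values lay on 1 side of the 3 untreated values, which largely follows from the threshold. The same held in 20.9% of all genes, where 10% is the share expected for unchanged genes on average over divisions of the arrays. Genes on the same arrays vary together, so 1 division can lie far from 10% without an effect. limma with Benjamini-Hochberg adjustment gave the 581 calls. The count was 294 without untreated culture 5, 250 without untreated culture 7 and 266 without untreated culture 8. It was 301 without treated culture 7 and 303 without treated culture 8, but 756 without treated culture 5. Whichever 1 culture was left out, 207 of the 581 genes kept the call. The highest adjusted p among these 207 was 0.010212, so each called gene with a larger adjusted p lost its call without at least 1 culture.

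**Figure D1:**
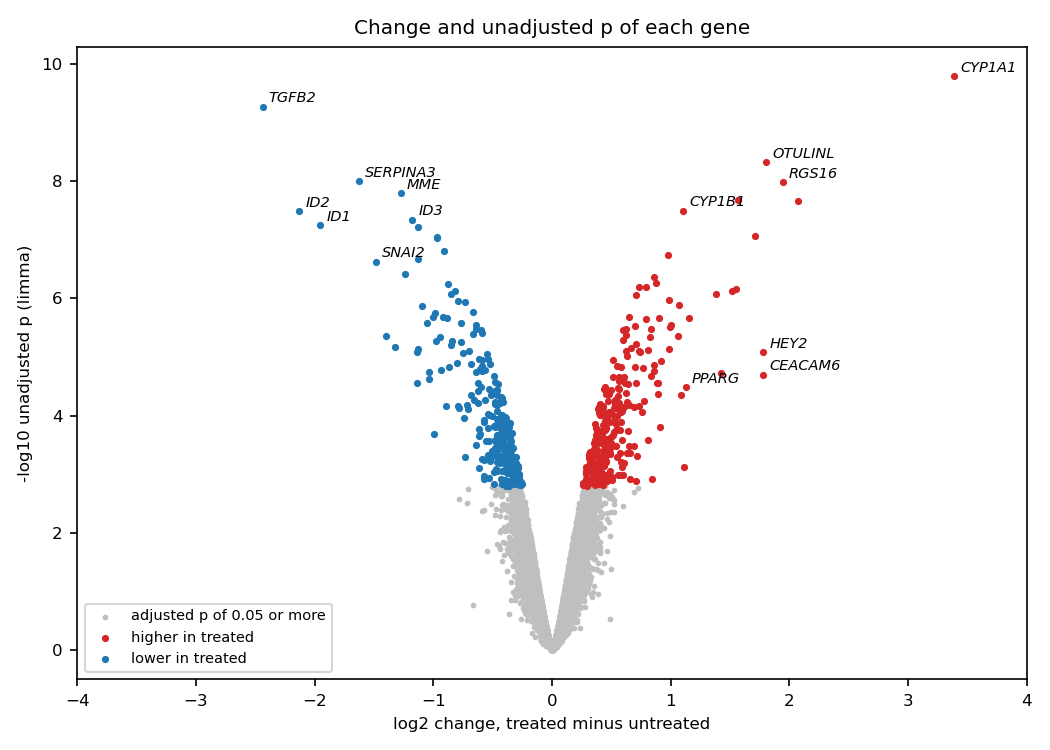
Change of each of the 18417 genes (x axis, log2, treated minus untreated) against the -log10 of its unadjusted limma p (y axis), with genes past an adjusted p of 0.05 coloured by direction. CYP1A1 stands farthest to the right at 3.39 and TGFB2 farthest to the left at -2.44.

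Targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor that responds to many planar aromatic compounds, were the list with the highest median change (0.24). Of its 10 measured members, 3 rose and none fell (6 rose and 1 fell when adjusted over the list alone). CYP1A1 went from 5.42 ± 0.24 to 8.80 ± 0.07 (SD, n = 3 each), a 10.5-fold rise (log2 change 3.39, SE 0.11; adjusted p = 2.9e-06). CYP1B1, another cytochrome P450 of this pathway, rose 2.15-fold from a high level (log2 change 1.11, SE 0.07; adjusted p = 6.0e-05). ALDH1A3, a retinaldehyde dehydrogenase, rose 1.75-fold (adjusted p = 0.017), and its second, dimmer probe set had a change of 0.28 that did not pass (adjusted p = 0.31). The receptor gene AHR itself had a change of 0.12 (adjusted p = 0.61), TIPARP one of 0.26 (adjusted p = 0.12), and NQO1, a quinone reductase, one of 0.23 (adjusted p = 0.086). Camera's adjusted p for the list was 4.9e-07 with the preset correlation, and adjusted p = 0.090 with an estimated correlation; fry's was 0.00099.

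Among the other large rises, RGS16, a regulator of G protein signalling, rose 3.85-fold from 7.93 ± 0.22 to 9.87 ± 0.05 (SD, n = 3 each; adjusted p = 3.9e-05). TARP, a transcript of the T cell receptor gamma locus, rose 4.22-fold by the probe set used (adjusted p = 5.0e-05). A further TARP probe set held identical values, and the only distinct one, at a mean of 4.55, had a change of 0.02. OTULINL rose 3.50-fold, HEY2, a transcriptional repressor downstream of Notch, 3.43-fold, BMPR1B, a bone morphogenetic protein receptor, 3.27-fold, and MICAL2, an actin-oxidising enzyme, 2.96-fold. NECAB1 and PPFIA2 rose 2.93-fold and 2.60-fold. The carcinoembryonic antigen family members CEACAM6 and CEACAM5 rose 3.43-fold and 2.86-fold, and C1QTNF9B rose 2.69-fold. These last 3 have close paralogs, so their signals may be shared with relatives on a hybridisation array. Adjusted p-values of these 9 genes ran from 2.9e-05 for OTULINL to 0.0034 for CEACAM6.

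Of the genes for the inhibitors of DNA binding, helix-loop-helix proteins that hold back differentiation and are classic targets of bone morphogenetic protein signalling, ID1, ID2 and ID3 fell. ID4 had a change of -0.47 that did not pass (adjusted p = 0.086). ID2 fell from 8.85 ± 0.15 to 6.72 ± 0.26 (SD, n = 3 each), 4.38-fold lower (adjusted p = 6.0e-05). ID1 was 3.88-fold lower (adjusted p = 8.5e-05) and ID3 2.26-fold lower (adjusted p = 7.6e-05). TGFB2 fell from 9.86 ± 0.08 to 7.42 ± 0.17 (SD, n = 3 each), 5.42-fold lower (log2 change -2.44, SE 0.09; adjusted p = 4.9e-06). SERPINA3, which encodes alpha-1-antichymotrypsin, was 3.09-fold lower, MME, which encodes the cell surface peptidase neprilysin, 2.42-fold lower, and KRT80, an epithelial keratin, 2.36-fold lower. MALL was 2.20-fold lower. MGP, which encodes matrix Gla protein, was 2.49-fold lower from a low level of 5.89 ± 0.35 (SD, n = 3). Adjusted p-values of these 5 genes lay between 3.9e-05 and 0.0019.

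Of 27 measured genes of basal and mesenchymal cells, 4 fell and none rose (5 fell when adjusted over the list alone, and 1 was higher and 10 lower at an unadjusted limma p below 0.05). SNAI2, which encodes the transcription factor SLUG, was 2.80-fold lower (adjusted p = 0.00022), ANXA1, which encodes annexin A1, 2.63-fold lower (adjusted p = 0.0013), CAV1, which encodes caveolin-1, 2.20-fold lower (adjusted p = 0.0042) and FN1, which encodes fibronectin, 1.80-fold lower (adjusted p = 0.00050). The median change over all 27 members was -0.07, and VIM, the vimentin gene, lay low in both groups (4.38 and 4.42). Camera gave the list an adjusted p of 0.0020, lost with an estimated correlation (adjusted p = 0.48), and fry an adjusted p of 0.079. Of 15 fibroblast markers, 2 rose and none fell (2 rose and 1 fell when adjusted over the list alone), with LUM, the lumican gene, 1.88-fold higher (adjusted p = 0.012) and COL3A1 1.26-fold higher (adjusted p = 0.046), while COL1A1 changed by -0.02 (adjusted p = 0.95).

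**Figure D2:**
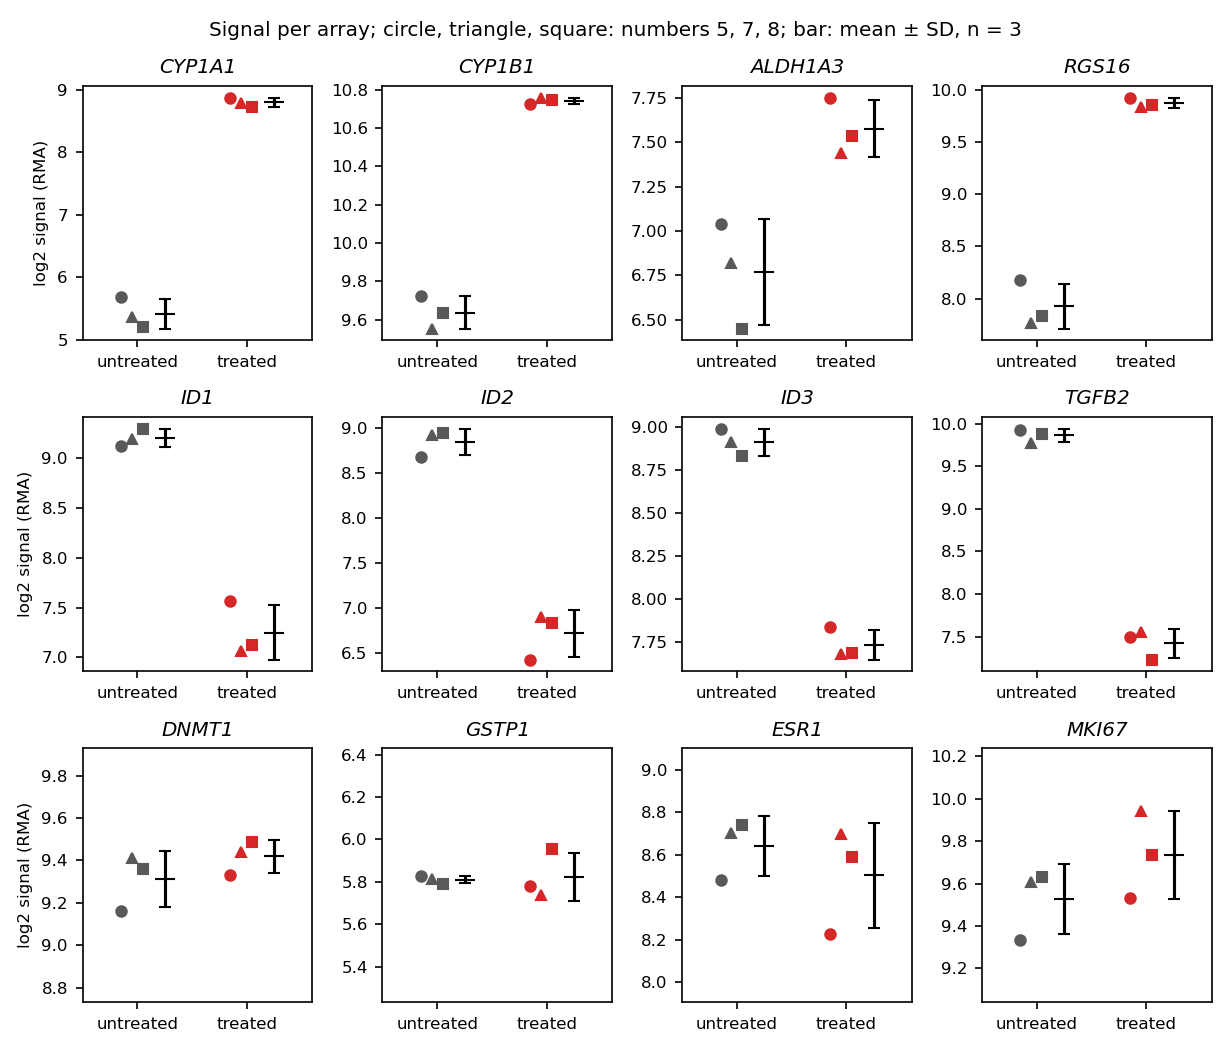
Signal of 12 genes in each array (y axes, log2 RMA signal, each panel on its own scale that does not start at 0), with untreated cultures in grey, treated in red, symbols for the numbers 5, 7 and 8, and the mean ± SD of 3 arrays in black. CYP1A1, CYP1B1, ALDH1A3 and RGS16 lie higher and ID1, ID2, ID3 and TGFB2 lower in every treated array, whereas DNMT1, GSTP1, ESR1 and MKI67 overlap between the groups.

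Genes reported to be promoter-methylated in breast tumours or cell lines did not rise as a group. Of 61 measured, none rose and 5 fell by limma (1 rose and 6 fell when adjusted over the list alone, and 5 were higher and 6 lower at an unadjusted p below 0.05), and the median change was -0.03. Those that fell were CAV1, DKK1 and THBS1, which encode a membrane scaffold, a Wnt antagonist and a matrix glycoprotein and were 2.20-fold, 1.80-fold and 1.76-fold lower, TFPI2 (1.34-fold) and CDKN2B (1.31-fold). All 5 lay above the median gene in mean signal, with untreated DKK1 at 9.54 ± 0.13 and THBS1 at 10.6 ± 0.07 (SD, n = 3 each). GSTP1, a glutathione transferase gene known to be methylated in MCF-7 cells, was at 5.81 ± 0.02 in untreated and 5.82 ± 0.11 in treated cells (SD, n = 3 each; log2 change 0.01, 95% interval -0.15 to 0.18; adjusted p = 0.95). RARB, the retinoic acid receptor beta gene, and CCND2, the cyclin D2 gene, had changes of -0.06 and -0.08 with adjusted p-values of 0.75 and 0.62. The list did not pass by camera (adjusted p = 0.51) or fry (adjusted p = 0.32).

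Cancer-testis and germline genes, many of which are held silent by methylation in somatic cells, mostly stayed at low levels. Of 42 measured, 3 rose and none fell, over all genes and also when adjusted over the list alone. These were ADAM2, a sperm surface protein gene (1.44-fold, adjusted p = 0.014), SYCP3, a synaptonemal complex gene (1.37-fold, adjusted p = 0.0087), and CTCFL, a germline paralog of CTCF (1.26-fold, adjusted p = 0.030). ADAM2 and SYCP3 reached 5.14 and 5.37 in treated cells, and both lay among the 30% of genes with the lowest mean signal. The CTCFL probe set used lay high in both groups, at 8.68 ± 0.09 in untreated and 9.01 ± 0.03 in treated cells (SD, n = 3 each). The other probe set of CTCFL, at a mean of 5.25, had a change of -0.29 (adjusted p = 0.14). The mean of both did not pass (adjusted p = 0.91, in a range of 0.0081 to 0.91 over the alternatives run for CTCFL). Which of them reads the CTCFL transcript was not tested, so a rise of this gene is not settled. The median change of the list was -0.0024 and camera's adjusted p was 0.51. Of this list, 12 of 54 genes, such as MAGEA3 and SSX2, had no probe set with a single symbol and were not analysed here.

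Among genes of the DNA methylation machinery, DNMT1 was at 9.31 ± 0.13 in untreated and 9.42 ± 0.08 in treated cells (SD, n = 3 each; log2 change 0.11, 95% interval -0.07 to 0.29; adjusted p = 0.60). UHRF1, which recruits DNMT1 to replicated DNA, had a change of 0.09 (adjusted p = 0.75), DNMT3A one of 0.0022 and DNMT3B one of 0.11 (adjusted p = 0.99 and 0.75). Of 20 measured members, 1 rose, both over all genes and adjusted over the list alone: IDH1, an isocitrate dehydrogenase gene, rose 1.32-fold (adjusted p = 0.0086). Camera's adjusted p for the list was 0.51.

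Targets of the oestrogen receptor went both ways. Of 39 measured, 4 rose and 4 fell (6 and 7 when adjusted over the list alone). CYP1B1, PKIB (1.71-fold, adjusted p = 0.0029), TFF3 (1.44-fold, adjusted p = 0.0075) and NRIP1 (1.25-fold, adjusted p = 0.029) rose. The call of CYP1B1 is the one already counted among aryl hydrocarbon receptor targets. CCN5 (1.54-fold, adjusted p = 0.013), CELSR2 (1.36-fold, adjusted p = 0.011), and the growth regulators MYC (1.28-fold, adjusted p = 0.028) and CCND1 (1.27-fold, adjusted p = 0.030) fell. The receptor gene ESR1 had a change of -0.14 (95% interval -0.41 to 0.14, adjusted p = 0.68). Without treated culture 5 the log2 change of ESR1 was 0.0021. PGR, low in both groups, had a change of 0.13 (adjusted p = 0.70), and TFF1 one of 0.37 (adjusted p = 0.11). Among 26 luminal epithelial genes, 1 fell, KRT7 (1.40-fold, adjusted p = 0.022), and none rose (1 fell and 1 rose when adjusted over the list alone), and the lineage factors GATA3 and FOXA1 had changes of -0.03 and 0.04. Camera's adjusted p was 0.79 for each of these lists.

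Of 54 measured cell cycle and DNA replication genes, 52 had a change above 0 and the median was 0.21, but only 3 rose, the mitotic genes MAD2L1 (1.34-fold, adjusted p = 0.012), BUB1 (1.27-fold, adjusted p = 0.031) and AURKA (1.25-fold, adjusted p = 0.027). When adjusted over the list alone, 18 rose. MKI67, the gene for the proliferation antigen Ki-67, had a change of 0.21 (adjusted p = 0.45). The mean signal over the list was 8.88, 9.03 and 9.03 in untreated cultures 5, 7 and 8 and 9.03, 9.30 and 9.25 in treated cultures 5, 7 and 8. Camera's adjusted p of 1.7e-15 was lost with an estimated correlation (adjusted p = 0.48), and fry's adjusted p was 0.17. Targets of p53, which is wild type in this line, were mixed: of 31, 2 rose and 2 fell (2 and 3 when adjusted over the list alone), with GDF15 1.61-fold and RPS27L 1.34-fold higher and CDKN1A, the p21 gene, 1.30-fold and PLK2 1.21-fold lower (adjusted p-values from 0.0073 to 0.041; camera's adjusted p for the list was 0.95).

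Of 19 measured genes of cholesterol synthesis, 5 rose and none fell (10 rose and 1 fell when adjusted over the list alone), with a median change of 0.18. INSIG1, a sterol sensor, rose 1.47-fold (adjusted p = 0.0058), SC5D 1.38-fold (adjusted p = 0.021), and MSMO1, HMGCS1 and IDI1, which encode enzymes of the pathway, 1.28-fold, 1.28-fold and 1.23-fold. Camera's adjusted p was 1.3e-08, lost with an estimated correlation (adjusted p = 0.36), and fry's adjusted p was 0.046. Of 23 genes of fatty acid synthesis and lipid storage, 2 rose and none fell (6 rose when adjusted over the list alone). PPARG, the gene for a lipid-sensing nuclear receptor, went from 7.67 ± 0.29 to 8.79 ± 0.22 (SD, n = 3 each), a 2.18-fold rise (adjusted p = 0.0047), and ACSL1, an acyl-CoA synthetase gene, rose 1.31-fold (adjusted p = 0.038). The list's adjusted p was 0.00095 by camera, 0.48 with an estimated correlation and 0.091 by fry.

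Of 43 measured interferon-stimulated genes, 4 fell and none rose (6 fell when adjusted over the list alone), and 31 had a change below 0, with a median of -0.09. IFI27 was 1.92-fold lower (adjusted p = 0.0030), IFI6 1.66-fold lower (adjusted p = 0.025), IRF9, a transcription factor of the response, 1.31-fold lower (adjusted p = 0.034), and IFIT2, near the lower end of the signal range, 1.29-fold lower (adjusted p = 0.0499). The list's adjusted p was 0.00048 by camera, lost with an estimated correlation (adjusted p = 0.30), and 0.079 by fry. STAT1 and STAT2 were not analysed here.

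Stress and inflammatory lists held few calls and none passed camera's test. Of 33 genes of the unfolded protein and integrated stress responses, 1 rose and 2 fell (1 and 8 when adjusted over the list alone; adjusted p = 0.059 by camera), with ASNS, asparagine synthetase, 1.70-fold lower (adjusted p = 0.0010), CHAC1 1.35-fold lower (adjusted p = 0.015) and DNAJC3 1.24-fold higher (adjusted p = 0.046). Of 25 NRF2 antioxidant genes, 2 rose and 1 fell (4 and 1 when adjusted over the list alone; camera's adjusted p = 0.29): GCLM, a subunit of glutamate-cysteine ligase, and AKR1C3 were 1.34-fold and 1.22-fold higher and the transporter gene ABCC3 1.63-fold lower. Of 34 hypoxia and glycolysis genes, HK2, a hexokinase gene, rose 1.27-fold and PFKFB3, which sets a glycolytic activator, was 1.56-fold lower (2 rose and 1 fell when adjusted over the list alone; camera's adjusted p = 0.79). Of 25 NF-kappaB and cytokine genes, only NFKBIA fell (1.27-fold, adjusted p = 0.020), over all genes and over the list alone (camera's adjusted p = 0.79). Of 11 metallothioneins and related genes, which are near-identical in sequence, MT1X fell 1.25-fold (adjusted p = 0.045; 1 rose and 1 fell when adjusted over the list alone; camera's adjusted p = 0.51). None of 22 heat shock genes passed by limma, over all genes or adjusted over the list alone, and 4 were higher and 1 lower at an unadjusted p below 0.05 (camera's adjusted p = 0.27); the smallest p-values were those of DNAJB4 (change -0.26, adjusted p = 0.11) and HSPA2 (change 0.19, adjusted p = 0.16).

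**Figure D3:**
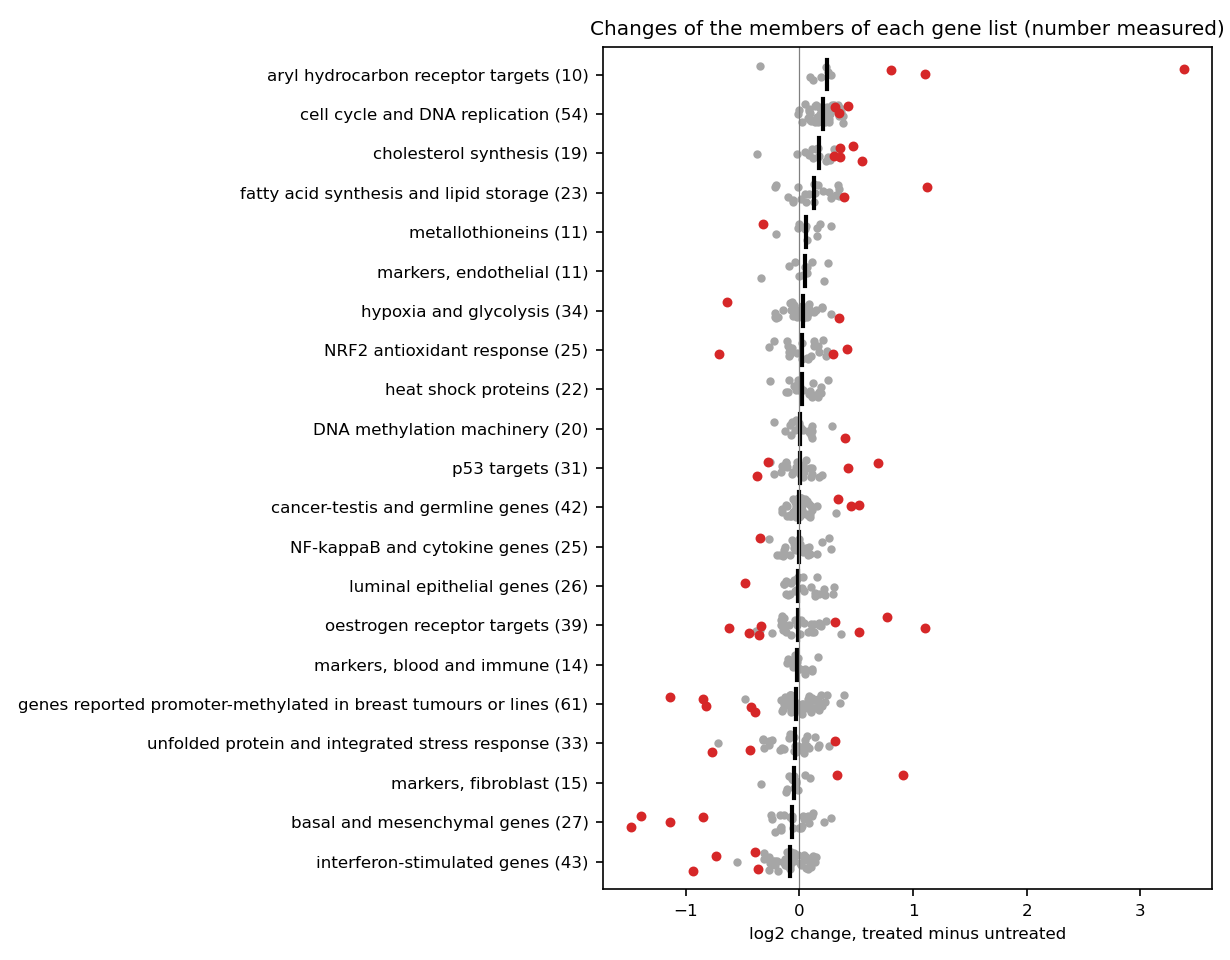
Changes (x axis, log2, treated minus untreated) of the measured members of the 18 lists and 3 marker lists (rows, number measured in brackets), with members past an adjusted p of 0.05 in red and the median as a black bar. Medians run from -0.09 for interferon-stimulated genes to 0.24 for aryl hydrocarbon receptor targets.

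None of 14 blood and immune markers and none of 11 endothelial markers passed by limma, over all genes or adjusted over the list alone. At an unadjusted p below 0.05 there were 0 of the former, and 2 higher and 1 lower of the latter. The smallest p-values were those of CD4 (change 0.16, adjusted p = 0.48), MS4A1 (-0.10, adjusted p = 0.56), CLDN5 (0.22, adjusted p = 0.19) and CDH5 (0.25, adjusted p = 0.21).

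In total 6 of the 18 lists passed camera's test with the preset correlation, 2 passed fry's (aryl hydrocarbon receptor targets and cholesterol synthesis) and 0 passed camera with an estimated correlation (2 at an unadjusted p below 0.05). By fry's mixed p, which takes either direction, 17 of the 18 lists passed, all but the cell cycle list. That test does not compare a list with other genes, and 2800 of all 18417 genes had an unadjusted limma p below 0.05. Even the heat shock list, without a called gene, passed it (adjusted p = 5.8e-05), so passing it does not set a list apart. The median, the mean and camera's direction differed in sign for cancer-testis, oestrogen receptor, p53, hypoxia and luminal genes, none of which passed. Dividing the 6 cultures another way, with untreated 5, treated 5 and untreated 8 on 1 side, gave 7 lists by the same camera test.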

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

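The tests of cell cycle spread and of fibroblast loss were chosen after the results had been seen.

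The same fit over every row of the table gave 54 probe sets with no listed gene or several genes that were higher in treated cultures past the adjusted threshold, and 17 that were lower, among 13837 such rows. Some share identical values, so the 54 hold 52 different signals. They were singled out because the named comparison leaves them out. Their genes are not named here.

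The number of genes past the threshold was 581 for treated against untreated, and 1 of the 10 ways to divide the arrays into 2 groups of 3 gave as many, the real one. The highest of the others was 0 genes by limma, with 398 to 1452 genes at an unadjusted p below 0.05 against 2800 for the real one. Each of the others has treated and untreated cultures on both sides. An effect of treatment would add to the spread within their groups and lower their counts, so they are no pure reference for chance. With 10 divisions a share under 0.05 cannot be reached. For the gene lists by camera with the preset correlation, 2 of the 10 divisions gave at least the real 6, and the highest other gave 7. That division set untreated 5, treated 5 and untreated 8 against the rest.

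The higher cell cycle genes may reflect differences in cycling between cultures as much as treatment. The list means overlapped between the groups, since treated culture 5 (9.027) lay just below untreated cultures 7 and 8 (9.032 each). The correlation estimated between the 54 members was 0.78. Within each number, however, the treated culture lay above the untreated one. Number 5 had 9.027 against 8.884, number 7 had 9.299 against 9.032 and number 8 had 9.255 against 9.032. No label says whether the numbers mark pairs. The difference of 0.21 ran from 0.16 without treated culture 7 to 0.29 without treated culture 5. Removing treated culture 5 also ended the overlap. It was the only treated culture that overlapped, so this had to follow whatever the cause. The adjusted p with an estimated correlation was between 0.33 and 0.70 whichever culture was left out. An effect of treatment on cycling stays open.

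A loss of fibroblast-like cells from the treated cultures was set against the lower SNAI2, ANXA1, CAV1 and FN1. Such cells would bring all their abundant transcripts, but VIM (4.38) and DCN (3.90) lay near the lower end of the signal range in untreated cultures. The 3 fibroblast markers above the median gene, COL1A1, COL3A1 and LUM, had changes of -0.02, 0.33 and 0.91, with -0.18 as the lowest 95% bound. The 95% interval of FN1 ran from -1.01 to -0.68. Of all 15 markers, 11 had a change below 0, but the median change was small (-0.05). The tables argue against this explanation. A change in the expression of the MCF-7 cells themselves was not tested apart from treatment.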

How the results depend on the processing

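The fits over every row and with the block and trend together were added after the data had been seen. The count of 581 genes was between 250 and 756 with 1 array left out, 931 with a variance trend, 306 when every row was tested, 1461 with the replicate block and a variance trend together, 944 at an adjusted p below 0.10 and 40 at 2-fold or more. The last 2 follow from the thresholds, and the cause of the others was not tested. With the replicate block it was 489, of which 432 were shared with the 581, and 12 genes named by the rule (CTCFL, TFPI2, IRF9, IFIT2, ACSL1, AKR1C3, DNAJC3, PLK2, HK2, MT1X, NFKBIA and COL3A1) were not called, nor were MYC, NRIP1, IDI1, DUSP4 and PTPN14. No label says what same-numbered arrays shared beyond the number. Their deviations from the group means correlated at 0.20 for number 5, -0.043 for number 7 and 0.072 for number 8. With 3 arrays of the other group to match, 3 of 6 arrays correlated best with their own number. These values do not settle whether the numbers mark pairs. Other scalings, the mean of probe sets, a robust prior, all annotated probe sets and the dim filter gave 562 to 670 genes. The 6 lists became 0 with an estimated correlation in camera and 2 with fry, for causes not tested, and were 6 or 7 under all other alternatives run on lists. Of the 81 named genes 67 passed the threshold, and 27 of these lost the call without at least 1 array, where fewer samples were tested (CDKN1A, MAD2L1, LUM, CCN5, ADAM2, CHAC1, ALDH1A3, MSMO1, NFKBIA, SC5D, KRT7, IFI6, AURKA, GCLM, CTCFL, BUB1, AKR1C3, HMGCS1, IRF9, ACSL1, PLK2, HK2, MT1X, COL3A1, DNAJC3, TFPI2 and IFIT2). So did CELSR2, MYC, NRIP1, CCND1, CDKN2B, IDI1, AJUBA, DOCK5, PTPN14, JUNB, KLF10, TIMP1, PHLDA1, DUSP4 and STRA6. The 24 with the largest changes kept it without any 1 array and under the other alternatives run on named genes, except that MGP was not tested without dim genes. TFF1 and NQO1 passed only with a variance trend. The stress response list passed with medians subtracted, when quantile-normalised again, and without untreated culture 5 or treated culture 7. Among results past the threshold 0 changed sign, but 2 named genes and 5 lists short of it did, the cause not being tested. With 1 array left out, the change of ESR1 ran from -0.23 to 0.0021 (above 0 without treated culture 5) and that of GSTP1 from -0.051 to 0.058 (below 0 without treated culture 8). By adjusted p, p53 targets turned upward with the block (0.968), with medians subtracted (0.991), and without untreated 5, untreated 8 or treated 8 (range 0.753 to 0.995 with each array left out). NF-kappaB genes turned upward without dim genes (0.964) and without untreated 5 or treated 8 (0.49 to 0.995). Oestrogen receptor targets turned upward with fry (0.902) and without treated 5, untreated 7 or untreated 8 (0.304 to 0.942). Luminal genes turned downward when quantile-normalised again (0.873) and without treated 7 (0.571 to 0.995), and hypoxia genes without treated 7 (0.678 to 0.995). RMA compresses changes of dim genes such as GSTP1, and no detection calls were at hand to tell a low level from background.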

Other observations

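The 6 lists in this part were written after the ranked genes had been seen, and genes high in that ranking, with called members of the earlier lists, were left out of each test. The 12 tested members that stand in an earlier list, such as ID4, RARB and COL1A1, were kept because they had not passed. The predictions were written before the values of the tested members were looked at, but that these 12 had not passed was already known. In all 6 lists every member left out had changed in the direction asked about. Leaving these out, and keeping 12 known not to have passed, works against each prediction. A test that did not pass therefore does not count against its pathway, and the medians describe only the remaining members.

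Some further genes that respond to transforming growth factor beta or to the YAP and TEAD transcription factors fell. Among YAP-TEAD targets, CCN1, a secreted matricellular protein gene, fell by 0.56 on the log2 scale (adjusted p = 0.0030), AMOTL1, an angiomotin, by 0.68 (adjusted p = 0.0027), AJUBA by 0.44 (adjusted p = 0.011), DOCK5 by 0.40 (adjusted p = 0.016) and PTPN14 by 0.31 (adjusted p = 0.046). Among transforming growth factor beta targets, SMAD7, a feedback inhibitor of the pathway, fell by 0.48 (adjusted p = 0.0051), LOXL2, a collagen cross-linking enzyme gene, by 0.53 (adjusted p = 0.0049), TIMP1 by 0.46 (adjusted p = 0.019), JUNB by 0.41 (adjusted p = 0.016) and KLF10 by 0.35 (adjusted p = 0.018). None of the tested members of these lists rose. Some members of other lists rose. PHLDA1 and DUSP4, which follow MAP kinase activity, rose by 0.64 and 0.36 (adjusted p = 0.013 and 0.049), against the fall asked about. STRA6, a retinol transporter gene, rose by 0.42 (adjusted p = 0.017). ACADM, an enzyme gene of fatty acid oxidation, rose by 0.47 (adjusted p = 0.0051). For the retinoic acid and PPAR lists that hold these genes, a rise was the direction asked about.

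Lower YAP-TEAD activity is a hypothesis for the fall of TGFB2, SNAI2, FN1 and THBS1. Only TGFB2 and THBS1 stand in the YAP-TEAD list, whereas all 4 stand in the list of transforming growth factor beta targets. Of 24 YAP-TEAD members tested, 2 of them known from an earlier list not to have passed, 19 had a change below 0 and 5 fell. The median was -0.17 (SE 0.048), but camera's adjusted p with an estimated correlation was 0.11, so the test was not decisive. For transforming growth factor beta targets the median was -0.069 (SE 0.041, 29 members, 5 fell, camera's adjusted p with an estimated correlation = 0.20). Of these 29, 4 stand in another of the 6 lists. With the preset correlation, camera's adjusted p was 5.9e-08 for YAP-TEAD and 0.00021 for transforming growth factor beta targets. It was 0.079 to 0.74 for the other 4 lists. The predictions named the estimated correlation, so the preset values do not decide them. Bone morphogenetic protein targets were a candidate explanation of the lower ID1, ID2 and ID3. Their median was -0.038 (SE 0.052, 17 members, camera's adjusted p with an estimated correlation = 0.40), and 1 fell, SMAD7. The 4 members left out, ID1, ID2, ID3 and MSX2, had all fallen, so this median describes only the rest. It stays open whether the ID genes moved with a pathway or apart from it.

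The other 3 lists gave medians near 0 and no decision. MAP kinase feedback targets, asked about because CCND1, MYC and ERRFI1 were lower, had a median of -0.025 (SE 0.059; 16 members; adjusted p = 0.80). Retinoic acid targets, asked about because DHRS3 and ALDH1A3 were higher, had a median of 0.060 (SE 0.053; 13 members; adjusted p = 0.20). Targets of PPAR receptors, asked about because PPARG was higher, had a median of 0.040 (SE 0.047; 23 members; adjusted p = 0.40).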
